A study of Equus caballus with 24 samples.

How the data were processed

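RNA was measured in 12 sarcoids, labelled tumour tissue, and 12 skin controls of the horse. Per the labels' protocols, material was kept in RNAlater at -80 °C, total RNA was isolated with TRIzol and a Direct-zol kit, ribosomal RNA was depleted, and libraries made with a Swift Rapid kit were indexed, combined in a single pool and read as paired ends on a NovaSeq. The submitters' processing notes name FastQC, TopHat2, HTSeq, DESeq2 and the EquCab3.0 build, without versions or settings. The strand setting and gene annotation release are not given in the sources used here.

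The deposited values are counts, whole numbers of reads per gene for 30371 Ensembl gene IDs, not normalized. Each file ends with 5 summary rows for reads in no gene, in several genes, of low alignment quality, not aligned, or aligned to several places, which held 72.6% to 86.6% of all rows' counts. Those rows stayed out of library sizes and tests. Reads aligned to several places are tallied in such a row and not in genes, so levels of genes with near-identical copies or overlapping or antisense partners are uncertain. The files do not pair IDs with names, and a reference table of 39335 horse genes matched 0 of the 30371 IDs. The gene lists and cell type markers fixed before the data were examined were therefore not tested, and checks of GC content and gene length are void because no gene had a value.

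Counts were analysed with R 4.3.3. Genes were kept by edgeR 4.0.16's filterByExpr with the group, leaving 14930. Libraries were scaled by TMM, with factors from 0.468 to 1.60, and groups were compared over all 24 libraries in 1 model with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Fold changes are sarcoid over skin. Their standard errors are the log2 fold change divided by the square root of the F statistic. Values per library are CPM on the scaled library sizes, and the log2 CPM used for principal components, correlations and positions had a prior count of 2.

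The rule for named genes took those with the largest rise and fall among genes with an adjusted p under 0.05, a mean of at least 2 on the log2 CPM scale and at least 11 of 12 libraries of one group beyond the median of the other. It asked for genes with a symbol and for 12 in each direction. With no symbols, 2 IDs per direction are given out of 2710 candidates that rose and 2802 that fell. Of the rest of the rule, parts that rest on gene lists were not applied.

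Differences of a single measure between groups were tested with two-sided permutation tests of 100000 resamples, and correlations likewise. Comparisons of library measures, counts of non-overlapping genes, positions between the groups and the correlations with them were not among the tests fixed before the data were examined. The biological coefficient of variation was fitted in each group alone, with a jackknife over libraries as its error. No pair of libraries differed by as little as sampling noise. The smallest chi-square per degree of freedom among the 276 pairs was 31.2, between skin 3 and skin 6. Shares of a single library carry 95% Wilson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

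The fit was tested on simulated data drawn from the real means and library sizes of the comparison of sarcoid with skin, over 14930 genes of which 14770 passed the filter. It recovered 55 of 99 genes changed by 1 on the log2 scale and 91 of 98 changed by 2, and it called 10 of 14573 unchanged genes. Genes were drawn independently of each other from a single mean profile, without the composition differences between the real libraries. Depth was at least 9673480 gene counts per library.

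Alternatives fixed before the data were examined were RLE and upper-quartile factors, library size alone, no filter, a filter of 1 CPM in 12 libraries, limma 3.58.1's voom with quality weights, voom with the specimen number as a random block, DESeq2 1.42.0, a test against a 2-fold change, thinning to the smallest library, leaving out each library, leaving out the titles with an L, and a block on the 5 specimen numbers that occur in both groups. A fit of the libraries with these numbers without the block was also fixed then. Further alternatives were chosen after seeing the data. One was voom without weights or block. The others left out skin 9 and skin 16, those and sarcoid 4, the 2 most abundant genes, or the 8 sarcoids without an L. Figures were drawn with matplotlib 3.10.9.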

Results

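Gene expression was measured by RNA sequencing in 24 tissue pieces from horses, 12 sarcoids and 12 skin controls. The equine sarcoid is a common skin tumour of horses. The number of reads counted in genes ranged from 9673480 to 31769803 per library, with a median of 13227887 over all libraries, 12288953 over the sarcoids and 14140532 over the skin. Libraries are named here by group and by the number in their title. A trailing L in 4 sarcoid titles is kept, and the labels do not say what it means. Titles number the specimens without saying that each came from a different animal, so p-values measure the spread between these pieces. The files do not pair the gene IDs with names, so genes are described as groups defined by their direction and size of change, and 4 are given by their ID.

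The comparison of sarcoid with skin asks which genes differ in level between the tumour and normal tissue. Of 14930 genes tested, 8091 (54.2%) differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes higher in sarcoid numbered 4165 and genes lower in sarcoid 3926. The median log2 fold change was 1.0 among the higher genes and -1.02 among the lower genes, and the median standard error of a called gene was 0.23. At 2-fold or more the directions were near balance, with 2085 genes higher and 1991 lower. Larger falls outnumbered larger rises. At 4-fold or more 990 genes were lower and 608 higher. The numbers were 386 and 163 at 8-fold or more, and 133 and 45 at 16-fold or more. These counts were not recomputed with skin 9 and skin 16 both left out. How far these libraries supply the difference was not tested. At 8-fold or more without skin 9 alone, 289 genes with a skin mean of at least 10 CPM were lower and 193 genes higher. Without skin 16 alone these numbers were 260 and 172. Only the lower genes were held to that mean, so the 2 directions cannot be compared here, nor with the 386 and 163 above. Leaving out any 1 skin library gave 260 to 294 such lower genes and 168 to 198 higher genes.

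**Figure D1:**
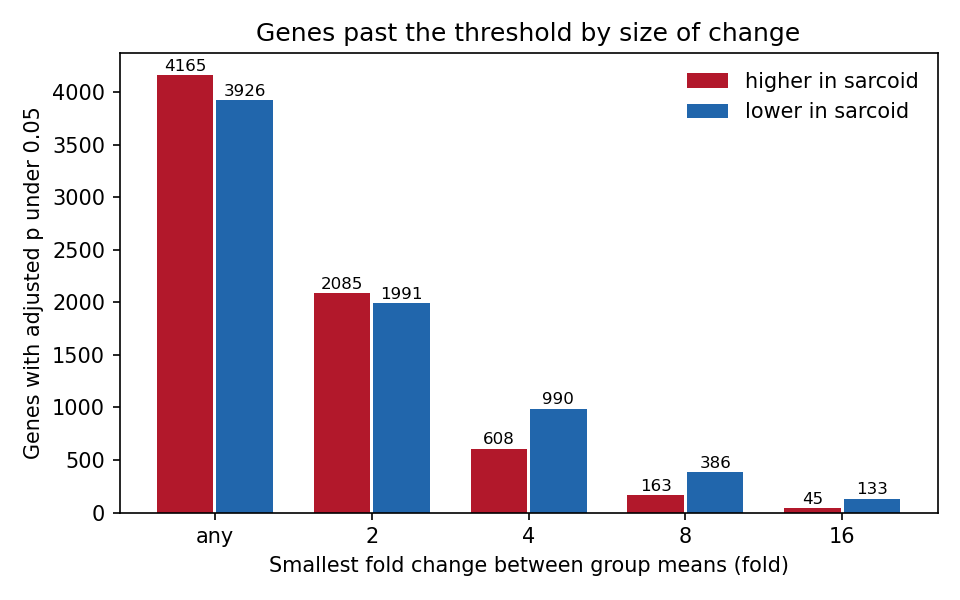
Number of genes with an adjusted p under 0.05 (vertical axis) at each smallest fold change between the groups (horizontal axis), with red bars for genes higher in sarcoid and blue bars for genes lower in sarcoid, 12 libraries per group. The bars are near equal at 2-fold, 2085 and 1991, and part at 16-fold, 45 and 133.

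Genes called higher in sarcoid took 36.7% ± 6.57 of the gene counts of a sarcoid library and 16.3% ± 4.95 of those of a skin library (mean ± SD, n = 12 each). Genes called lower took 9.68% ± 4.79 in sarcoid and 27.1% ± 6.63 in skin. These shares describe genes chosen on the same libraries. Both groups of called genes were found at every abundance. Of 117 genes with an average below 0 on the log2 CPM scale 31.6% were called, against 60.0% of the 2338 genes above 6. No gene was above 1 CPM in at least 11 libraries of one group and below 0.1 CPM in at least 11 of the other, so under that rule no gene was switched on or off between the groups. At the scaled sizes of several libraries 0.1 CPM is a single count or less, so the rule asks for almost no reads there.

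In 428 genes every sarcoid library lay above every skin library, and in 241 genes every sarcoid library lay below every skin library. Chance separates the groups in this way in 7.4e-05% of genes, or 0.011 of the 14930 tested. Each of these counts moved by over 1.5 times with a single library: 784 genes had every sarcoid below every skin library without skin 9, and 663 had every sarcoid above every skin library without sarcoid 2. When libraries were scaled by their total alone, 2116 genes were called higher and 3645 lower, and the median log2 fold change of all genes moved from 0.017 to -0.21. The near balance of the directions is relative to the composition scaling used.

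The rule for naming genes gave ENSECAG00000023733 and ENSECAG00000015342 as the largest rises. ENSECAG00000023733 averaged 441 ± 775 CPM in sarcoid and 2.73 ± 3.36 CPM in skin (SD, n = 12 each), a log2 fold change of 7.34 ± 1.13 (SE, edgeR adjusted p = 1.15e-05). All 12 sarcoids lay above the skin median of 1.82 CPM, and 9 of them above the highest skin library. Its level differed widely among the tumours, from 5.05 CPM in sarcoid 10 to 2473 CPM in sarcoid 9. The log2 fold change was 6.56 without sarcoid 9 and 7.93 without skin 2.

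ENSECAG00000015342 averaged 159 ± 247 CPM in sarcoid and 1.82 ± 2.57 CPM in skin (SD, n = 12 each), a log2 fold change of 6.47 ± 1.22 (SE, edgeR adjusted p = 1.15e-04). The rise was carried by 6 sarcoids that lay above the highest skin library, at 58.8 to 748 CPM. These were sarcoids 65L, 67L, 71L, 74L, 2 and 9, and the other 6 sarcoids lay between 0.625 and 2.03 CPM. All 4 tumours with an L in the title were among the first 6. That pattern was noticed after the values were seen. The 4 tumours with an L against the other 8 gave a log2 fold change of 2.41 ± 1.57 (SE) for ENSECAG00000015342, which did not pass the threshold (edgeR adjusted p = 0.644).

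The largest falls under the rule were ENSECAG00000024667 and ENSECAG00000019844. ENSECAG00000024667 had a log2 fold change of -12.20 ± 2.37 (SE, edgeR adjusted p = 1.58e-04), with means of 0.551 ± 1.41 CPM in sarcoid and 2818 ± 7893 CPM in skin (SD, n = 12 each). Its skin mean came mainly from skin 9, at 27159 CPM, and skin 16, at 6558 CPM. Skin 1 and skin 19 followed at 65.5 and 23.3 CPM, and the other 8 skin libraries lay between 0.885 and 2.41 CPM. The medians were 1.75 CPM in skin and 0.118 CPM in sarcoid, and 5 sarcoids had no count. The log2 fold change of ENSECAG00000024667 was -9.96 without skin 9, -14.16 without sarcoid 2 and -4.06 (edgeR adjusted p = 0.00194) without skin 9 and skin 16.

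ENSECAG00000019844 had a log2 fold change of -11.11 ± 1.98 (SE, edgeR adjusted p = 6.00e-05), with means of 0.406 ± 0.675 CPM in sarcoid and 984 ± 2782 CPM in skin (SD, n = 12 each). Skin 9 and skin 16 again stood highest, at 9612 and 2084 CPM, and skin 1 and skin 19 lay at 73.1 and 16.3 CPM. The other 8 skin libraries lay between 1.62 and 3.41 CPM, and 11 of the 12 sarcoids lay below the lowest skin library. The log2 fold change of ENSECAG00000019844 was -8.78 without skin 9, -12.03 without sarcoid 2 and -4.60 (edgeR adjusted p = 9.85e-05) without skin 9 and skin 16. The edgeR fit called a fall in both genes with and without these skin libraries, while its size depended on them. Under limma's voom with quality weights and all libraries kept, the log2 fold changes of the 4 named genes were smaller, 6.12 for ENSECAG00000023733, 4.19 for ENSECAG00000015342, -4.60 for ENSECAG00000024667 and -4.42 for ENSECAG00000019844. In voom without weights and without a block, ENSECAG00000015342 (4.27, adjusted p = 0.0502), ENSECAG00000024667 (-6.20, adjusted p = 0.0991) and ENSECAG00000019844 (-5.78, adjusted p = 0.0724) did not pass. With the specimen number as a random block in unweighted voom they did not pass either (adjusted p = 0.0505, 0.0980 and 0.0703), so the block is not what ended these calls there. Nor did they pass in edgeR with the number as a block over the 10 libraries that share it (adjusted p = 0.372, 0.404 and 0.281). In the same 10 libraries without the block, only ENSECAG00000019844 of the 3 passed (adjusted p = 0.0411).

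**Figure D2:**
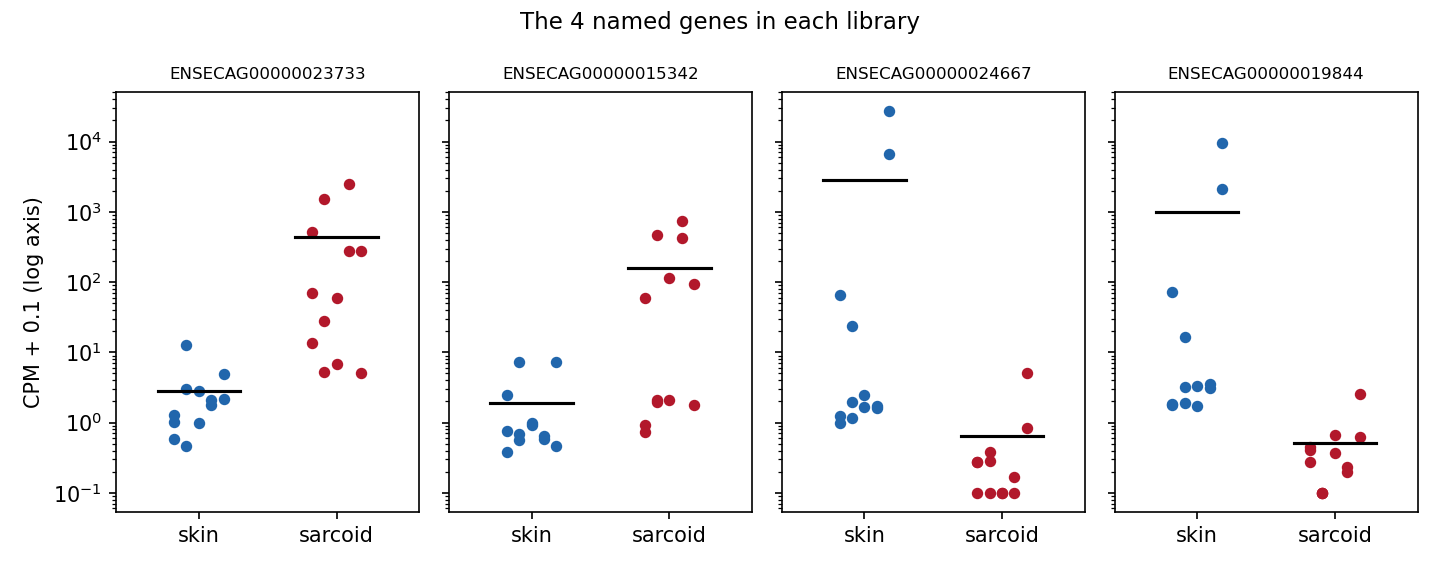
Level of the 4 named genes in each library, as CPM + 0.1 on a log axis, with a point per library (blue for skin, red for sarcoid, 12 each) and a black line at the group mean. Skin 9 and skin 16 lie at 27159 and 6558 CPM of ENSECAG00000024667, while 8 skin libraries lie at 2.41 CPM or less.

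A pair of genes, singled out after their values were seen, took a large and variable part of the counts. Neither passed the threshold between the groups, with errors that leave a 2-fold difference possible. ENSECAG00000034602 took 21.0% ± 10.3 of the gene counts in sarcoid and 17.8% ± 7.67 in skin (SD, n = 12 each). Its log2 fold change was 0.49 ± 0.67 (SE, edgeR adjusted p = 0.560), with single libraries between 7.41% in sarcoid 2 (95% Wilson interval 7.39 to 7.42) and 39.6% in sarcoid 12 (39.59 to 39.64). ENSECAG00000029964 took 6.30% ± 5.98 in sarcoid and 7.58% ± 9.51 in skin. Its log2 fold change was -0.46 ± 0.92 (SE, edgeR adjusted p = 0.695), and it reached 30.3% in skin 15 (95% Wilson interval 30.26 to 30.30).

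Fewer genes were detected in sarcoid, 19397 ± 1024 with at least 1 count against 20654 ± 1091 in skin (SD, n = 12 each). The difference of -1257 genes passed a two-sided permutation test (p = 0.00521, adjusted p = 0.0417 over 8 library measures compared). With every library thinned to the 9673480 counts of the smallest, the difference was -907 genes (permutation p = 0.0369), which did not pass the same adjustment (adjusted p = 0.295). The call was also lost when any 1 of 17 libraries was left out (adjusted permutation p up to 0.0971), so it lies near the threshold. None of the other 7 measures, which were shares of reads in 1 gene, in no gene, in several genes, aligned nowhere or aligned to several places, and of counts in the 2 most abundant genes, passed the adjusted threshold (lowest adjusted p = 0.619, two-sided permutation tests).

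In the median, replicates of one group were more alike than libraries of different groups. The median Spearman correlation was 0.915 between sarcoids, 0.952 between skin libraries and 0.807 between a sarcoid and a skin library. The first principal component held 52.1% of the variance and the second 8.6%. The biological coefficient of variation was 0.545 in sarcoid (jackknife SE 0.055) and 0.442 in skin (jackknife SE 0.078), a difference that was not tested. It was 0.493 in sarcoid without sarcoid 4 and 0.370 in skin without skin 9.

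The size of the change differed among the tumours, for the genes that rose and for those that fell. Each library was placed between the groups with the genes called at 2-fold or more when that library was left out, where 0 is the mean of the remaining skin and 1 the mean of the remaining sarcoids. On the higher genes the sarcoids lay between 0.53 (sarcoid 2) and 1.23 (sarcoid 12). On the lower genes they lay between 0.44 (sarcoid 6) and 1.46 (sarcoid 4). Of the lower genes with a change of 8-fold or more and a skin mean of at least 10 CPM, 265 to 357 genes by the sarcoid left out, between 26.0% (sarcoid 10) and 98.2% (sarcoid 3) were at or below an eighth of the skin mean in a given sarcoid. The same share was 78.9% in skin 9, 33.1% in skin 16 and 7.96% to 16.3% in the remaining skin libraries. The lowest sarcoid thus lay below skin 9 and skin 16 but above the rest of the skin libraries. Unless left out themselves, skin 9 and skin 16 are part of the skin mean used here and raise it in some genes. ENSECAG00000024667, for example, had a skin mean of 2818 CPM and a skin median of 1.75 CPM. Leaving out skin 9, the skin libraries lay between -0.28 and 0.15 on the higher genes and between -0.17 and 0.06 on the lower genes.

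The 2 positions rose together within the sarcoids. Pearson's r was 0.94 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 7e-05) and Spearman's rho 0.93 (permutation p = 3e-05), with r = 0.93 after leaving out sarcoids 2 and 6. In a family of 7 relations over the 12 sarcoids, the position on the lower genes fell with the number of genes detected (r = -0.84, permutation p = 9e-05, adjusted p = 0.000315, rho = -0.90, permutation p = 0.00017) and kept r = -0.87 without sarcoids 4 and 2. It also fell with the share of reads outside annotated genes (r = -0.76, permutation p = 0.00115, adjusted p = 0.00268, rho = -0.67, permutation p = 0.0205). Without sarcoids 4 and 2 that relation gave r = -0.67 and no longer passed (adjusted permutation p = 0.0582). The number of genes detected includes the lower genes that set this position. A tumour that has lost their counts detects fewer genes, so the relation with that number is partly built in.

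The relation of the same position with the count share of ENSECAG00000034602 (r = 0.70, permutation p = 0.0119, adjusted p = 0.0208, rho = 0.72, permutation p = 0.0108) passed over all 12 tumours. Without sarcoids 12 and 4 the relation gave r = 0.50 and did not pass (adjusted permutation p = 0.243). The share of reads aligned to several places behaved alike (r = 0.54, permutation p = 0.0246, adjusted p = 0.0345, rho = 0.70, permutation p = 0.0147), with r = 0.34 without sarcoids 4 and 12 (adjusted permutation p = 0.453). Library depth on the log2 scale (r = 0.49, permutation p = 0.110, rho = 0.48, permutation p = 0.115, r = 0.12 without sarcoids 12 and 2) and the share of ENSECAG00000029964 (r = 0.07, permutation p = 0.824, rho = 0.01, permutation p = 0.991, r = 0.18 without sarcoids 65L and 3) did not pass. Within the 8 tumours without an L in the title, r was 0.94 between the positions, -0.92 with the number of genes detected, -0.85 with the share of reads outside annotated genes, 0.88 with the share of ENSECAG00000034602 and 0.64 with the share of reads aligned to several places.

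**Figure D3:**
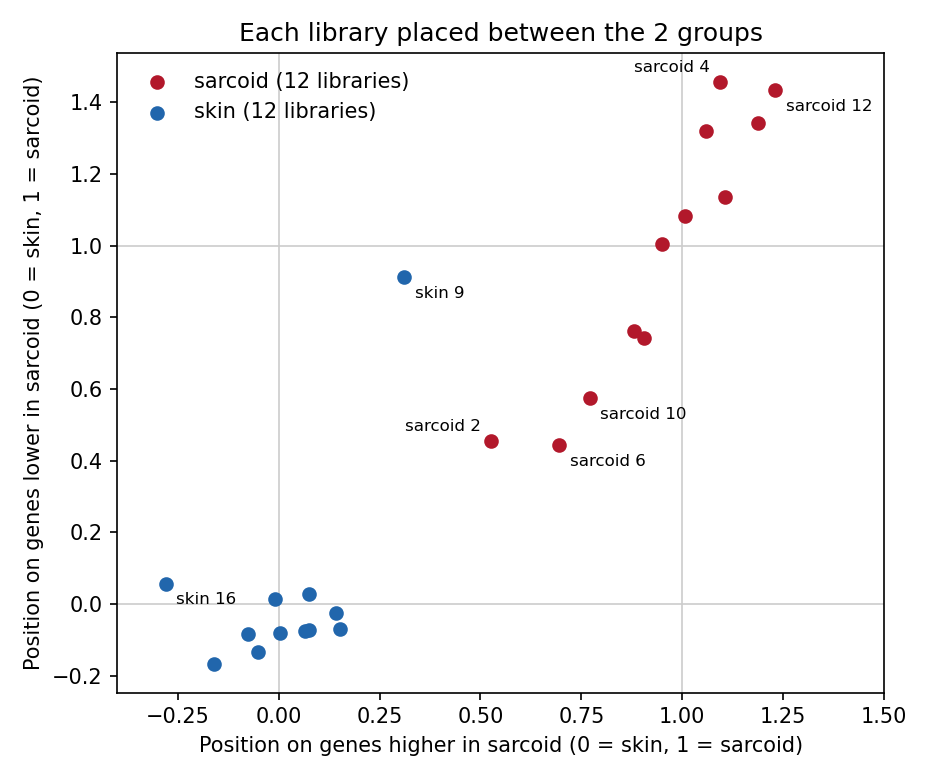
Position of each library between the group means on genes higher in sarcoid (horizontal axis) and lower in sarcoid (vertical axis), unitless, with 0 the mean of the other skin libraries and 1 the mean of the other sarcoids. Red points are sarcoids and blue points skin, and skin 9 lies at 0.31 and 0.91, apart from both groups.

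Skin 9 stood apart from the other skin libraries mainly on the genes lower in sarcoid. It lay at 0.91 there, against at most 0.06 in the other skin libraries. On the genes higher in sarcoid it lay at 0.31, with the other skin libraries between -0.28 and 0.15. Its median Spearman correlation was 0.793 with the other skin libraries and 0.822 with the sarcoids. In skin 9, 79 genes at 20 CPM or more and at least 20 times the median of the other libraries held 26.8% of the counts (95% Wilson interval 26.7 to 26.8). The same 79 genes held 4.10% of the counts of skin 16 (4.09 to 4.11), 0.507% of those of skin 1 (0.503 to 0.510) and between 0.0199% and 0.134% in the other 21 libraries. One of these genes alone took 18.6% of the counts of skin 9 (18.59 to 18.62), 2.54% of those of skin 16 (2.53 to 2.55) and 0.293% of those of skin 1 (0.291 to 0.296). Without skin 9, 8304 genes passed the threshold between sarcoid and skin, 4317 higher and 3987 lower, and without skin 9, skin 16 and sarcoid 4 the number was 8277.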

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

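The tests of a wrong label, of count share taken by few genes, of carry-over and of a uniform share of skin were chosen only after the patterns were seen. Chance assignment of libraries was tested by other splits. Of 100 splits of the 24 libraries into 12 and 12, only the real split, 1 of the 100, gave as many as its 8091 genes. The highest of the others called 655 genes, with 9 sarcoids on one side. Chance assignment is thus an unlikely source of the count, to the 1 in 100 that these splits can resolve. The splits take the pieces as independent.

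Reads outside the gene counts stood above the highest skin library in a few sarcoids. In sarcoid 4, 23.9% of reads aligned to several places (95% Wilson interval 23.87 to 23.89), against at most 6.87% in skin. There 5.996% of reads fell in several genes (5.991 to 6.001), against at most 1.82% in skin, and 48.6% did not align (48.61 to 48.63), against at most 48.5%. In sarcoid 12, 8.81% of reads aligned to several places (8.799 to 8.813). In sarcoid 2, 35.9% of reads lay outside annotated genes (35.93 to 35.95), against at most 35.6% in skin. In the other direction, that share was only 8.11% in sarcoid 4 and 15.9% in sarcoid 12, against at least 19.2% in skin.

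Skin 9 lay apart from the other skin libraries. A sarcoid under a skin label was not settled. On the genes higher in sarcoid, skin 9 lay at 0.31, below the lowest sarcoid, 0.53. That gap exceeded the SD of 0.13 over the other 11 skin libraries but was close to the SD of 0.21 over the sarcoids. Of the genes higher by 8-fold or more, 2.07% reached that rise in skin 9. This share was 0% to 4.86% in the other skin libraries and 19.1% to 80% in the sarcoids. On the lower genes its 0.91 lay within the sarcoid range of 0.44 to 1.46. Its median Spearman correlation was 0.822 with the sarcoids and 0.793 with skin. The position on the genes that rose thus argues against a wrong label, while that on the genes that fell does not. The 2 largest falls, ENSECAG00000024667 and ENSECAG00000019844, stood at 27159 and 9612 CPM in skin 9. No sarcoid had more than 4.99 and 2.46 CPM of them, though their fold changes rested partly on skin 9. Loss of counts to a few genes is argued against. The genes lower in sarcoid fell by 2.05 in the median on the log2 scale of unscaled CPM with a pseudocount of 0.5. The 26.8% of counts held by 79 genes lowers the rest by only -0.45. Depth did not account for it, as the position on the lower genes was 0.95 after thinning, against at most 0.04 in the other skin libraries. Material of another kind in the piece stays open and was not tested, since the files give no gene names from which to read markers.

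The genes high in skin 9 were raised in skin 16. All libraries were read in a single pool, so carry-over of skin 9 material or reads into skin 16 was weighed. Carry-over of a fixed share of RNA or reads sets a floor on the ratio of skin 16 to skin 9 in every gene, since expression of its own can only add to it. Of the 79 genes, 11 had an upper 95% counting bound of 0.0631 or less, over 4 times below the median ratio of 0.254. This argues against such carry-over as the whole source, with bounds set after the ratios were seen; carry-over of an uneven part of the tissue was not tested. That the pair of skin pieces shared a tissue component is a hypothesis, and no biological explanation was tested.

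The sarcoids spread along the axis from skin to sarcoid on rising and falling genes alike. The share of counts in the most abundant gene and the share of reads outside annotated genes are argued against as the whole source, since the positions kept partial correlations of 0.88 (permutation p = 0.00016) and 0.87 (permutation p = 0.00027) once each was regressed out over 12 sarcoids. A uniform share of ordinary skin in the tumour piece cannot be told apart from graded tumour expression. In the 5 sarcoids that kept 5.46% to 20.2% of the skin level of the lower genes, the higher genes lay below the level that such a share predicts by a median of -0.21 log2 units, with an SD of 0.18, and the bound used, 0.2 exceeded by more than the SD, was set after that value was seen and would have been passed without the SD. Differences between the tumours themselves may also contribute and were not tested.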

How the results depend on the processing

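Settings with voom without weights or block, with the 2 most abundant genes removed, with named libraries left out together, with only the L titles, and those of the numbers of genes detected and of non-overlapping genes were chosen after seeing the data. The count of 8091 genes stayed within 1.5 times under 39 of 42 alternatives. Leaving out each of the 24 libraries gave 7797 to 8304 genes. RLE gave 8073, DESeq2 10362 with 5748 adjusted p-values not given, voom with quality weights 8583 and without 7612, thinned counts 7740, the 8 sarcoids without an L 7703, the 4 with an L 6992, and without skin 9 and skin 16 8235. Of the 8091 genes, 95.9% remained called by DESeq2 and 91.6% by voom with quality weights.

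Counts of genes called between sarcoid and skin over all 24 libraries that moved by over 1.5 times were these. Library size alone gave 2116 higher genes; the cause was not tested. Without a filter, 3300 genes were higher and 3569 lower at 2-fold or more, and DESeq2, with more genes tested, gave 3324 lower at 2-fold or more. The test against a 2-fold change, a stricter question by construction, gave 2092 genes, 989 higher and 1103 lower.

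The labels do not say whether the 5 specimen numbers shared by the groups mean the same horse. Deviations of same-numbered libraries correlated at -0.02, 0.06, 0.16, 0.49 and -0.03, and 1 of 5 correlated best with its own number. With the number as a block over those 10 libraries, 1996 genes were called, 1085 higher and 911 lower, with 850 and 767 at 2-fold or more. The same 10 libraries without the block gave 2504, 1473 higher and 1031 lower, with 1034 and 708 at 2-fold or more, so most of the loss was there without the block. These libraries are fewer and also hold skin 9 and sarcoids 2 and 6, which lay at 0.91, 0.45 and 0.44 on the lower genes. The number of libraries and the choice of them were not told apart.

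The named genes kept their direction, but their sizes moved. Beyond leaving out 1 library, log2 fold changes ranged from 5.32 to 7.79 for ENSECAG00000023733, 2.46 to 7.59 for ENSECAG00000015342, -14.37 to -3.99 for ENSECAG00000024667 and -11.80 to -3.50 for ENSECAG00000019844. The smallest sizes came with the block over 10 libraries, except for ENSECAG00000024667, where leaving out skin 9, skin 16 and sarcoid 4 gave the smallest. ENSECAG00000023733 passed under all 42 alternatives. The other 3 missed the threshold in unweighted voom with and without a block and in the block over 10 libraries, and ENSECAG00000015342 and ENSECAG00000024667 also in the 10 libraries without it, with adjusted p up to 0.404. The difference in genes detected kept its direction in all 28 alternatives but passed the adjusted threshold in only 9. It missed it in thinned libraries (-907) and without the L titles (-1331). Leaving out each of the 24 libraries gave -1394 to -1035, and 17 of these missed it. Alternatives that concern gene lists were not run. The simulation recovered 55.6% of the genes changed by 2-fold. It changed 200 genes, against 8091 called in the real comparison, so its adjusted threshold was stricter. It also drew genes independently, so neither recovery of small changes nor the rate of false calls in the real comparison was measured.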

Other observations

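The genes lower in sarcoid varied together among the tumours. The first component of the 1991 genes lower by 2-fold or more held 64.5% of their variance over the 12 sarcoids, against 31.4% for the 2085 genes higher by 2-fold or more, 32.01% for 6839 genes not called and 10.6% for shuffled values of the lower genes. In skin the same lower genes gave 64.7%, and 49.6% without skin 9. The median SD of a gene on the log2 scale within sarcoid was 1.12 among the lower genes, 0.80 among the higher genes and 0.51 among genes not called.

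Sarcoid 4 held 20 genes at least 10 times above every other library, skin 16 held 14 and skin 9 held 5, and no other library held more than 3. In sarcoid 4, 87 genes at 20 CPM or more and at least 20 times the median of the other libraries took 13.5% of the counts.

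The 4 tumours with an L in the title were set against the other 8, a comparison chosen after seeing the data. No gene passed the threshold in edgeR's quasi-likelihood test, with 1382 of 15246 genes at an unadjusted p under 0.05, and voom with quality weights also called 0, while DESeq2 called 121. Over 100 of the 495 splits of the tumours into 4 and 8, all 100 gave at least as many genes by construction, since the split by title gave 0, so the splits say nothing about chance. The highest of the other splits called 700 genes.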
